A study of Homo sapiens with 12 samples.

How the data were processed

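RNA sequencing was done on 12 libraries of 769-P, an established human clear cell renal carcinoma cell line. The libraries form 4 groups of 3, which the labels name siDRAIC, siDRAIC-NC, sihnRNPA2B1 and sihnRNPA2B1-NC. The NC groups are taken here as the controls of the siRNA (small interfering RNA) named with them. What the letters NC stand for, and the sequences of the siRNAs, are not given in the sources used here.

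The deposited values are raw read counts per Ensembl gene, 1 whole number per gene and library, in a table for each siRNA experiment. Total RNA was taken with RNAiso Plus and made into libraries with a TruSeq kit, per the labels' protocols. Per the submitters' processing notes, the genome build was hg38 and the tools included fastp 0.23.2, STAR 2.7.10a, StringTie and DESeq2, with no version given for the last 2. The program that counted reads, its annotation and whether it used strand are not given in the sources used here. Reads of overlapping genes on opposite strands therefore cannot be told apart. Reads of near-identical copies (histone genes, ribosomal protein genes and their pseudogenes, mitochondrial genes and their nuclear copies, HNRNPA1 and HNRNPA3, AKR1B10 and AKR1C3) could be split or lost in ways the counts do not show, so the levels of such genes are uncertain.

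Both tables hold the same 60617 gene IDs, of which 60261 were paired with a symbol by a table of gene names and 58542 are in GENCODE 29, the source of coordinates on GRCh38. A count in at least 1 library was found for 33780 IDs. There were 0 lines that name no gene and 0 unused columns of sample values. Library totals ran from 30798303 to 42760528 counts, with 21927 to 24055 genes above 0. The totals, the 3 libraries per group and the spread between them set the precision; 3 counts in 1 library correspond to 0.0702 to 0.0974 CPM (counts scaled to the library total). Intervals and floors cover counting error only. Libraries of the same group differed by far more than sampling noise over genes with a summed count of 100 or more, with a chi-square per degree of freedom of 4.94 to 139.8, so no library was counted as a copy of another.

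Each experiment was fitted apart with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr at its minimum count of 10, scaled by TMM factors and tested two-sided with the robust quasi-likelihood test, and p-values were adjusted by the Benjamini-Hochberg method over all tested genes. A gene is called changed when its adjusted p is below 0.05. Log2 fold changes are siRNA over its own control, and their standard errors (SE) are approximate, taken as the absolute log2 fold change over the square root of the F statistic. The difference between the changes of the 2 experiments was tested on all 12 libraries with 4 group means, as the change in the libraries labelled siDRAIC minus the change after hnRNPA2B1 siRNA. CPM are given as mean ± SD of 3 libraries. DRAIC fell below the expression filter in both experiments, so the planned test gave no value for it, and its summed counts are compared as a ratio with an exact 95% interval.

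A total of 33 gene lists of 12 to 46 members were written down from general knowledge before the data were examined, as were the tests, the alternatives and the rule for naming genes; 1 listed symbol, SOD2, had no ID in the tables. Lists with at least 5 tested members were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) at its preset inter-gene correlation of 0.01, adjusted over the 29 such lists. Counts of called members are also given adjusted over the list alone. The genes named are DRAIC, HNRNPA2B1 and IGF1R; up to 8 rising and 8 falling genes per siRNA with the smallest p among those called, at least 2-fold changed (absolute log2 fold change of 1), separated in every library and at a mean of 2 CPM or more; and up to 4 called members with the smallest p of each list past its test and of the m6A, hnRNP and insulin-like growth factor lists. For the difference of effects, the 5 genes with the smallest p on each side at a difference of at least 1 and 2 CPM are named, and for genes called in both experiments up to 5 per combination of directions. Any other gene named was chosen after its values were seen. Some called list members are counted but not reported here by name.

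The alternatives were RLE size factors, DESeq2 1.42.0, limma-voom, no low-count filter, a filter of 1 CPM in 3 libraries, the replicate number as a block, all 12 libraries in 1 fit, a 2-fold threshold, each library left out in turn and, for the lists, camera with an estimated correlation and fry. The groups share replicate numbers, so their pairing was checked as the correlation of deviations from the group means. In the DRAIC experiment the same-numbered pairs gave 0.489, 0.227 and 0.277 and the other pairs between -0.409 and 0.103. All 3 lie above 0.1 and above every other pair, though the highest other pair, at 0.103, also passes 0.1. The numbers are taken to pair those samples. The pairing comes from these same values, since the labels give only a number. All blocked p-values for the DRAIC experiment therefore hold only if the numbers do pair the samples. Blocked values are given beside the DRAIC results they change.

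The procedures were tested on simulated counts with 200 genes changed by known folds. The real counts had first been fitted before that test was written. For the DRAIC experiment edgeR recovered 2%, 12%, 54% and 94% of genes changed 1.25, 1.5, 2 and 4-fold, and 15.6% of its calls were false, which is above the nominal 5%; DESeq2 gave 25.8% and limma-voom 17.4% false calls. With the replicate block the shares recovered there were 6%, 22%, 84% and 100%, with 0.935% false. The counts for the blocked fit were simulated from the block model, and those for the unblocked fits without pairs. Their shares of false calls therefore cannot be set against each other. For the hnRNPA2B1 experiment 66%, 90%, 96% and 100% were recovered with 4.35% false, and for the difference of effects 96% at 4-fold with 3.03% false. The simulation of the difference gave both experiments the same spread per gene. Fitted apart, their biological coefficients of variation were 0.242 (DRAIC) and 0.0642 (hnRNPA2B1), so the 3.03% may not hold for the real test. Of 100 unchanged simulated lists, camera put 0 (DRAIC) and 1 (hnRNPA2B1) below 0.05. The simulated genes were drawn independently of each other, so this cannot show how camera behaves for lists whose members are correlated.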

Results

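Gene expression was measured by RNA sequencing in 769-P renal carcinoma cells treated with an siRNA against the long non-coding RNA DRAIC or an siRNA against the RNA-binding protein hnRNPA2B1. Each siRNA had control libraries of its own, labelled siDRAIC-NC and sihnRNPA2B1-NC, and each of the 4 groups held 3 libraries. Summed counts were 35221570 to 39921513 in the siDRAIC-NC libraries, 36096920 to 42760528 in siDRAIC, 30798303 to 39362360 in sihnRNPA2B1-NC and 34064129 to 39367842 in sihnRNPA2B1. Levels are given as mean ± SD (n = 3). The labels do not say whether replicates were separate cultures, so all p-values measure only the spread between these samples, which may be technical.

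The title of the series ties DRAIC to hnRNPA2B1, a nuclear protein that binds RNA and is known as a reader of the m6A mark, and to IGF1R, the receptor for insulin-like growth factors. The RNA of these 3 genes was therefore examined first. HNRNPA2B1 RNA fell after its siRNA, and IGF1R RNA rose slightly in the same libraries and stood higher, close to the threshold, in the libraries labelled siDRAIC. DRAIC itself was too rare to be followed in either experiment.

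DRAIC (ENSG00000245750; chromosome 15, 69463026 to 69843120, plus strand, GRCh38; annotated as a lincRNA in GENCODE 29, with exons overlapping AC100826.1) had 3, 6 and 0 counts in the siDRAIC libraries and 2, 1 and 2 in siDRAIC-NC. RefSeq places DRAIC at 69561720 to 69571440 on GRCh38, within that span. Which model the counting used is not given in the sources used here, so these counts may include reads from outside the shorter locus. The summed counts of 9 against 5 gave a ratio of 1.76, with an exact 95% interval of 0.531 to 6.70. In the hnRNPA2B1 experiment it had 8, 6 and 2 counts with the siRNA and 7, 3 and 7 in the controls, 16 against 17, a ratio of 0.892 with an exact interval of 0.422 to 1.88. A knockdown of DRAIC was therefore not detectable at this depth, and the group is called the libraries labelled siDRAIC throughout. HNRNPA2B1 (ENSG00000122566; chromosome 7, 26173057 to 26201529, minus strand, overlapping CBX3) stood at 291 ± 16.7 CPM after its siRNA against 419.6 ± 21.0 in the controls, 0.677 times their level. The log2 fold change was -0.56 (SE 0.05, edgeR adjusted p = 2.2e-09). In the libraries labelled siDRAIC the same gene measured 664 ± 115 CPM against 779 ± 116 (log2 fold change -0.25, SE 0.16, edgeR adjusted p = 0.622), a difference within the spread between replicates.

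IGF1R (ENSG00000140443; chromosome 15, 98648539 to 98964530, plus strand) measured 48.9 ± 1.37 CPM in the libraries labelled siDRAIC and 26.0 ± 5.90 in their controls, a 1.86-fold higher level. Its log2 fold change of 0.89 (SE 0.19) just missed the threshold in edgeR (adjusted p = 0.0538). With the replicate number as a block it was 0.91 and passed (edgeR adjusted p = 4.85e-06), which holds only if the numbers pair the samples. It also passed with DESeq2 (0.87, adjusted p = 0.0023) and in edgeR without the low-count filter (0.87, adjusted p = 0.00529). Without siDRAIC-NC replicate 1 it passed in edgeR too (1.02, adjusted p = 0.00773). It failed with RLE factors (edgeR adjusted p = 0.0593), limma-voom (0.0757) and the strict filter (edgeR adjusted p = 0.0611). With any other single library left out it failed as well (edgeR adjusted p of 0.132 to 0.303). Over all alternatives the adjusted p ran from 4.85e-06 to 0.303. After hnRNPA2B1 siRNA, IGF1R rose from 22.6 ± 1.44 to 27.8 ± 2.41 CPM, or 1.20-fold (log2 fold change 0.26, SE 0.08, edgeR adjusted p = 0.0188). That call was lost without sihnRNPA2B1-NC replicate 1 (adjusted p = 0.126), without sihnRNPA2B1 replicate 1 (0.0889) and without sihnRNPA2B1 replicate 3 (0.104). The 2 changes of IGF1R differed by 0.60 (SE 0.19), which did not pass the test of the difference (edgeR adjusted p = 0.294).

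**Figure D1:**
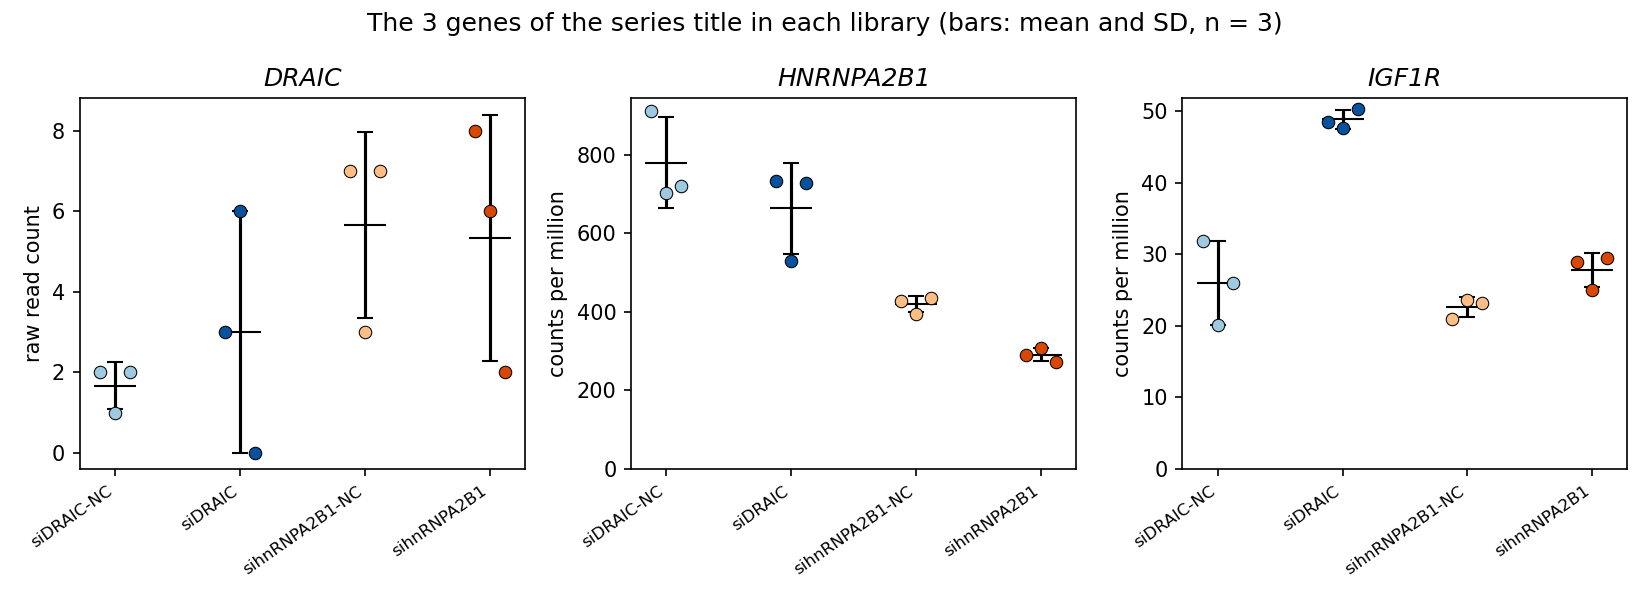
Raw read counts of DRAIC and CPM of HNRNPA2B1 and IGF1R in each of the 12 libraries (points), with the mean and SD of the 3 libraries of each group. HNRNPA2B1 lies at 291 CPM after its siRNA against 419.6 in its controls, IGF1R at 48.9 CPM in the siDRAIC libraries against 26.0, and DRAIC at 8 counts or fewer everywhere.

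In the libraries labelled siDRAIC, CXCL12 and MMP2 were among the genes that rose and CD74 among those that fell. CXCL12 (ENSG00000107562; chromosome 10, 44370165 to 44386493), a chemokine that signals through CXCR4, went from 0.879 ± 0.510 to 21.4 ± 5.87 CPM. MMP2 (ENSG00000087245; chromosome 16, 55389700 to 55506691, overlapping AC007336.3), a matrix-degrading gelatinase, went from 7.41 ± 4.16 to 68.5 ± 13.9 CPM. CD74 (ENSG00000019582; chromosome 5, 150401637 to 150412929), the invariant chain of MHC class II, dropped from 15.1 ± 7.88 to 0.839 ± 0.127 CPM. A total of 114 of 15986 tested genes were called (93 up, 21 down), 103 of them at least 2-fold changed.

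The log2 fold changes were 4.61 for CXCL12 (SE 0.39, edgeR adjusted p = 0.000716) and 3.21 for MMP2 (SE 0.33, edgeR adjusted p = 0.00271). NTS, the precursor of neurotensin, had 506 summed counts against 2, a ratio of 248 with an exact 95% interval of 68.3 to 2054. The secreted carboxypeptidase CPA4 rose from 3.22 ± 0.629 to 22.1 ± 8.31 CPM, and DIO3, the deiodinase that inactivates thyroid hormone, from 0.248 ± 0.0854 to 5.54 ± 3.11 CPM. MAF, a bZIP transcription factor, rose by 2.14 on the log2 scale. SLIT3, a guidance ligand of ROBO receptors, rose by 1.59, and EDIL3, an integrin-binding matrix protein, by 1.69. Among the genes that fell, CD74 changed by -4.19 (SE 0.40, edgeR adjusted p = 0.000814), the lysosomal protease CTSS by -3.06 and the lysosomal membrane protein LAPTM5 by -2.86. The membrane carbonic anhydrase CA12 (ENSG00000074410; chromosome 15, 63321378 to 63382161) went from 165 ± 21.5 to 64.2 ± 18.0 CPM, a change of -1.38 (SE 0.23, edgeR adjusted p = 0.0203). The aldo-keto reductase AKR1B10 (-1.74), the long non-coding RNA UCA1 (-1.22), AMBP, which encodes alpha-1-microglobulin (-1.96), and the amino acid transporter SLC6A15 (-1.48) completed the genes named by rule.

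With the replicate block, edgeR called 1404 genes (832 up, 572 down) and kept all 114, while DESeq2 called 381, limma-voom 45, edgeR without a filter 520, with the stricter filter 61 and in a fit of all 12 libraries 665 (418 up, 247 down). Leaving out 1 library gave 1035 calls (501 up, 534 down) without siDRAIC-NC replicate 1, where risers no longer outnumbered fallers, 9 without siDRAIC-NC replicate 2, 15 without siDRAIC-NC replicate 3, 95, 31 and 23 without siDRAIC replicates 1, 2 and 3. The calls of CXCL12, NTS, CPA4, DIO3, MMP2, CD74 and CTSS were kept in every one of these, and the other 22 of 29 genes named for this experiment lost theirs in at least 1. Calls lost numbered 1 (SGK1, edgeR adjusted p = 0.0967), 21 (0.0558 to 0.262) and 20 (0.0539 to 0.259) without siDRAIC-NC replicates 1, 2 and 3, and 8 (0.053 to 0.118), 14 (0.0594 to 0.234) and 17 (0.0531 to 0.17) without siDRAIC replicates 1, 2 and 3. In 15.6% of tested genes the groups did not overlap, where chance gives 10%.

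Among the gene lists, 13 of 29 passed camera in the libraries labelled siDRAIC, 3 upward and 10 downward. None passed with an estimated correlation, where 3 were below 0.05 unadjusted, or with fry, where 9 were. Replication-dependent histone genes, whose mRNAs end in a stem-loop in place of a poly(A) tail, rose as a list (camera adjusted p = 7.29e-07; adjusted p = 0.291 with an estimated correlation). Of 12 tested members H2AC6 (log2 fold change 1.94) and H2BC5 (1.66) were called, and 9 rose adjusted over the list alone. The extracellular matrix list also moved upward (camera adjusted p = 0.0151; adjusted p = 0.44 with an estimated correlation), with 4 of 24 members called, 5 up adjusted over the list alone and 0 down. These were THBS1, a matrix glycoprotein that overlaps FSIP1 (716 ± 155 against 289.7 ± 45.0 CPM, log2 fold change 1.29), the microfibril protein FBN1 (2.05) and the collagen chains COL6A3 (1.54) and COL1A1 (1.91). The 13 mitochondrially encoded mRNAs were higher as a list (camera adjusted p = 0.0308; adjusted p = 0.606 with an estimated correlation; 0.0538 with the block) with no member called, adjusted over the list alone or not. With the block, 7 histone genes rose, and 6 matrix genes rose and 2 fell. The share of counts from mitochondrially encoded mRNAs was 8.48 ± 0.796% in the libraries labelled siDRAIC against 7.07 ± 0.314% in siDRAIC-NC.

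Cell cycle lists moved downward together. The G2/M list had estimates below 0 in 34 of 36 members (camera adjusted p = 0.000327; adjusted p = 0.325 with an estimated correlation) and the G1/S list in 28 of 32 (camera adjusted p = 0.00284; adjusted p = 0.44 with an estimated correlation). No member of either passed edgeR, adjusted over the list alone or not, while the block called 9 and 1 down. Unblocked edgeR without siDRAIC-NC replicate 1 called 6 and 1 down. Cytosolic ribosomal proteins lay below 0 in 43 of 46 members (camera adjusted p = 0.000327; adjusted p = 0.55 with an estimated correlation) and the hnRNP family in 26 of 28 (camera adjusted p = 0.00546; adjusted p = 0.44 with an estimated correlation), again with no member called, adjusted over the list alone or not. In the ATF4 and unfolded protein list (camera adjusted p = 0.00284; adjusted p = 0.291 with an estimated correlation), 1 of 29 members fell, the pseudokinase TRIB3 (111 ± 7.60 against 199 ± 29.4 CPM), and 2 adjusted over the list alone, TRIB3 and the serine synthesis enzyme PSAT1. Cholesterol synthesis genes (24 tested, 0 called adjusted over the list alone) moved down (camera adjusted p = 0.00357; adjusted p = 0.44 with an estimated correlation). NF-kB targets (20 tested) did so as well (camera adjusted p = 0.00546; adjusted p = 0.55 with an estimated correlation). None of these was called over all genes, and 1 rose (VCAM1) and 1 fell (MMP9) adjusted over the list alone, while the block called 2 up and 10 down. With the block, 1 ribosomal protein gene and 4 cholesterol genes fell, and in the ATF4 list 1 rose and 5 fell. Unblocked edgeR without siDRAIC-NC replicate 1 called 4 ribosomal protein, 1 hnRNP, 2 cholesterol and 3 ATF4 list genes down. In the NF-kB list that fit called 1 up and 6 down.

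The neuronal markers (6 tested; camera adjusted p = 0.0255; adjusted p = 0.398 with an estimated correlation), heat shock genes (16 tested; 0.0272; adjusted p = 0.44 with an estimated correlation) and glycolysis genes (19 tested; 0.0437; adjusted p = 0.55 with an estimated correlation) also went down, with no member called over all genes. Adjusted over the list alone, the neuronal markers NEFL and RBFOX3 fell and no heat shock or glycolysis gene was called; the block called 2 neuronal markers and 1 heat shock gene down and 1 glycolysis gene in each direction. With the block the neuronal and glycolysis lists both had an adjusted p of 0.0854, and 10 lists passed. The histone, G2/M, G1/S, ribosomal protein and ATF4 lists passed camera without any 1 library. The others failed in the following cases. Without siDRAIC-NC replicate 1 these were the matrix (adjusted p = 0.102), heat shock (0.149), mitochondrial (0.386) and neuronal (0.0773) lists; without siDRAIC-NC replicate 2 the NF-kB (0.0824), glycolysis (0.1198) and neuronal (0.103) lists; without siDRAIC-NC replicate 3 the glycolysis (0.181), heat shock (0.0572) and mitochondrial (0.117) lists. Without siDRAIC replicate 1 they were the glycolysis (0.152) and mitochondrial (0.0808) lists; without siDRAIC replicate 3 the glycolysis (0.133) and matrix (0.0888) lists. Without siDRAIC replicate 2, where 7 lists passed, they were the hnRNP (0.0873), cholesterol (0.0739), matrix (0.0816), heat shock (0.242), mitochondrial (0.235) and neuronal (0.107) lists.

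The other 16 tested lists did not pass in the libraries labelled siDRAIC. The m6A machinery (camera adjusted p = 0.429) and SR splicing factors (0.594) had no called member, also adjusted over the list alone. The insulin-like growth factor list (0.153) had no member called over all genes; adjusted over the list alone, IGF1R, IGFBP3, IGFBP7 and the adaptor IRS1 rose and IRS2 fell. In the epithelial-mesenchymal list (0.447; median -0.01, mean 0.17, test upward), MMP2 and the integrin ITGB3 rose, with 5 up and 2 down adjusted over the list alone. CA12 fell in the hypoxia list (0.153; 4 down adjusted over the list alone), the triglyceride synthesis enzyme DGAT2 in the fatty acid list (0.0952; 1 down adjusted over the list alone), and the cadherin CDH6 rose among kidney epithelial genes (0.545; 1 up and 1 down adjusted over the list alone). No member was called in the p53 (0.102), autophagy (0.589), oxidative phosphorylation (0.429), apoptosis (0.891; median -0.03, mean 0.02, test downward), receptor tyrosine kinase (0.811; median 0.09, mean 0.11, test downward) and small non-coding RNA (0.404) lists, adjusted over the list alone or not. Adjusted over the list alone, the interferon list (0.404) had IFI44 and IFI6 up and BST2 down, the YAP/TEAD list (0.429) 3 up and 1 down and the immediate early list (0.447) FOSL1 down, with none called over all genes. Of markers of other cell types, COL1A1 was called among 3 fibroblast markers, and none among 3 blood and immune, 3 endothelial and 2 hepatocyte markers; adjusted over the list alone PDGFRB rose with COL1A1, and CSF1R, TIE1 and SERPINA1 fell. With the block, the members called up and down were 5 and 1 in the insulin-like growth factor list, 6 and 2 in the epithelial-mesenchymal, 2 and 5 in the hypoxia, 2 and 1 in the kidney, 3 and 1 in the p53, 3 and 2 in the autophagy, 2 and 1 in the apoptosis, 1 and 2 in the receptor tyrosine kinase, 3 and 2 in the interferon, 4 and 1 in the YAP/TEAD and 3 and 1 in the immediate early list. It also called 1 gene down in each of the m6A, oxidative phosphorylation, blood and immune and hepatocyte lists and 2 fibroblast markers up. ITGB3 and DGAT2, and the members named here only from adjustment over the list alone, were chosen after their values were seen. Without siDRAIC-NC replicate 2 (adjusted p = 0.00983) or siDRAIC replicate 1 (0.0492) the fatty acid list passed, and without siDRAIC replicate 3 the kidney list did (0.0423).

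After hnRNPA2B1 siRNA the tight junction gene CLDN2 (ENSG00000165376; chromosome X, 106900164 to 106930861, overlapping RIPPLY1) rose from 33.4 ± 1.96 to 106 ± 13.9 CPM, and the kidney cadherin CDH6 (ENSG00000113361; chromosome 5, 31193750 to 31329146) from 7.99 ± 0.749 to 30.9 ± 3.55 CPM. ARHGEF37 fell from 50.2 ± 1.93 to 14.7 ± 0.490 CPM. By camera the G2/M, NF-kB and YAP/TEAD lists fell and the lists of mitochondrially encoded mRNAs and histone genes rose. All 5 passed fry as well but lost the call in camera at adjusted p = 0.44 with an estimated correlation for the NF-kB list and adjusted p = 0.372 with an estimated correlation for each of the others. Of 15710 tested genes, 4781 or 30.4% were called (2366 up, 2415 down), 449 of them at least 2-fold changed (306 up, 143 down).

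The log2 fold changes were 1.62 for CLDN2 (SE 0.08, edgeR adjusted p = 2.7e-15), 1.92 for CDH6 (SE 0.10, edgeR adjusted p = 1.2e-14) and -1.80 for ARHGEF37 (SE 0.08, edgeR adjusted p = 1.9e-16). Further genes that rose were the ephrin receptor EPHA7 (2.18), VAV3 (1.63), the extracellular glycoprotein RELN (1.34), the mitochondrial proline tRNA gene MT-TP (1.22), the aldo-keto reductase AKR1C3 (1.16) and the arrestin-domain protein ARRDC3 (1.05). RELN, at 1.12 (edgeR adjusted p = 0.0405), was also called in the libraries labelled siDRAIC. Lower after hnRNPA2B1 siRNA were the inflammasome sensor NLRP1 (-1.53), the laminin chain LAMB3 (-1.23), the co-stimulatory receptor TNFRSF9 (-1.18), the Rab regulator TBC1D2 (-1.09), the ubiquitin ligase MARCHF4 (-1.05), the long non-coding RNA CASC19 (-1.04) and ITPRIP (-1.03), which binds the inositol trisphosphate receptor. The groups did not overlap in 42.0% of tested genes, where chance gives 10%. In a fit of all 12 libraries, with 1 shared estimate of spread, 283 genes (186 up, 97 down) were called after hnRNPA2B1 siRNA and 665 in the libraries labelled siDRAIC. Fitted apart, the biological coefficient of variation was 0.0642 and 0.242. Besides HNRNPA2B1, which kept its call without any 1 library, and IGF1R, whose losses are given above, 73 results were named for this experiment. Of these, 70 kept the call without any 1 library; IGF2BP3 (edgeR adjusted p = 0.0518) and GRB2 (0.0852) lost it without sihnRNPA2B1 replicate 1 and TXNDC5 (0.0784) without sihnRNPA2B1-NC replicate 2.

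**Figure D2:**
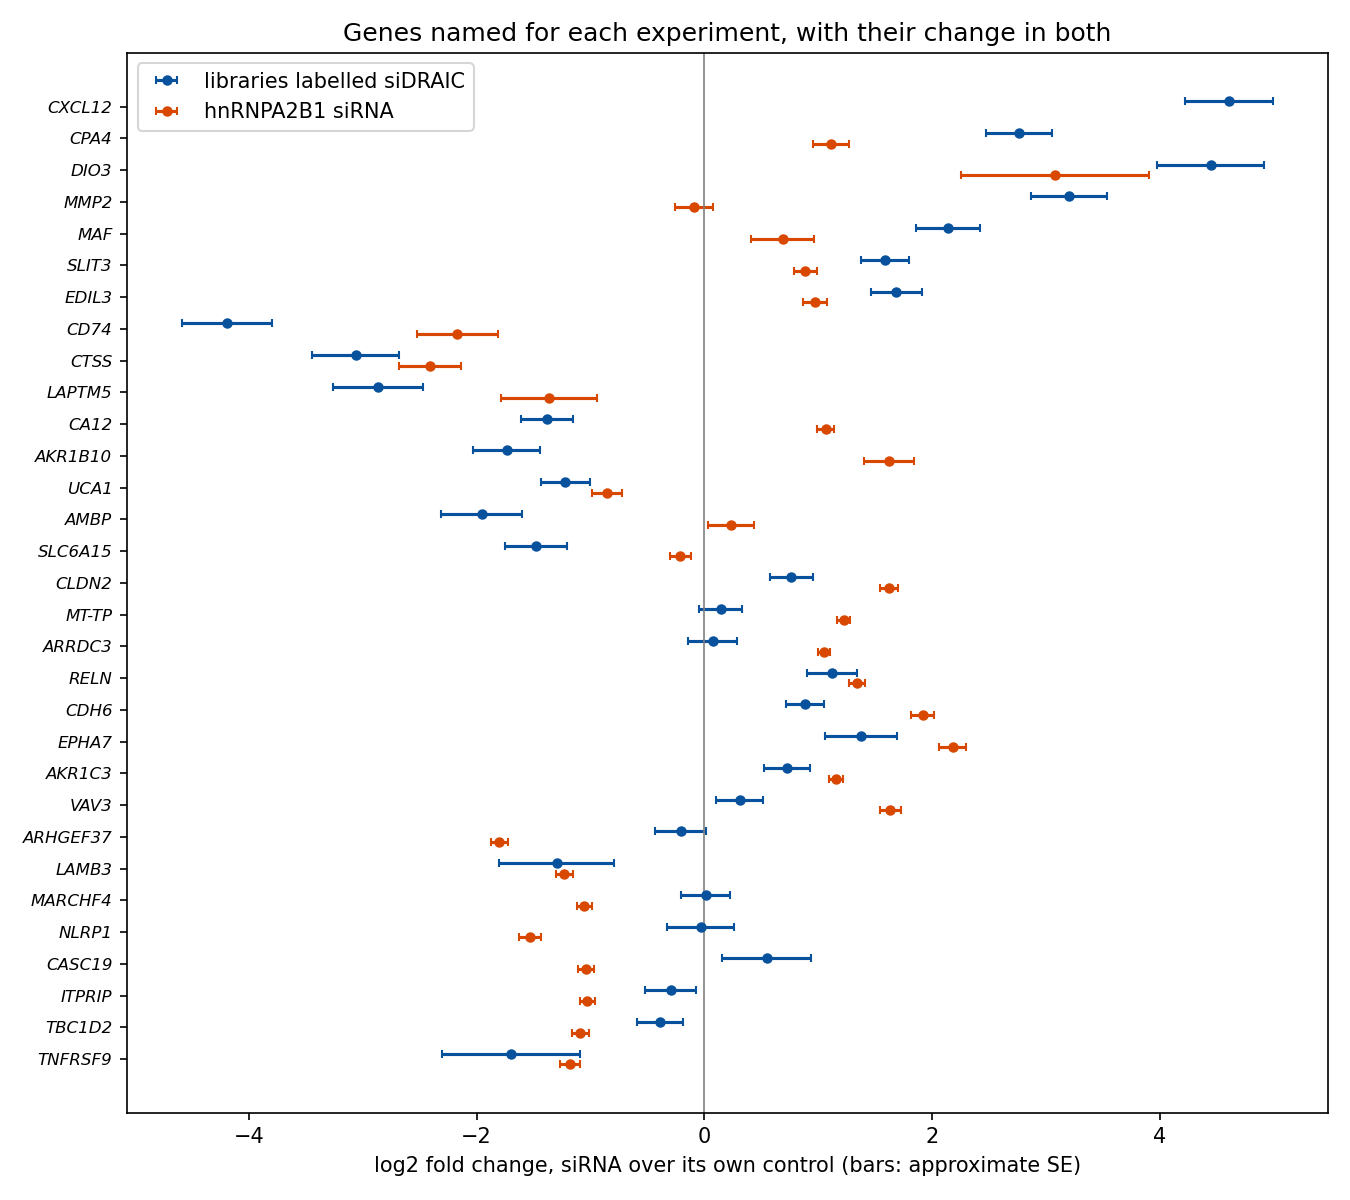
Log2 fold change of genes named for each experiment (horizontal axis) in the libraries labelled siDRAIC (blue) and after hnRNPA2B1 siRNA (orange), with approximate SE as bars; NTS, with 2 control counts, is left out, and CXCL12 was not tested after hnRNPA2B1 siRNA. CD74 and CTSS lie below 0 in both, at -4.19 and -3.06 in the libraries labelled siDRAIC, and CA12 lies at -1.38 and 1.07 on opposite sides.

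Genes related to the target itself moved in both directions, in an experiment where 30.4% of all tested genes were called. In the hnRNP family, 3 of 28 members rose (HNRNPA3 by 0.62, HNRNPA1 by 0.39 and SYNCRIP) and 9 fell, among them the splicing regulators PTBP1 (-0.32) and HNRNPM (-0.29), with the same counts adjusted over the list alone (camera adjusted p = 0.550). HNRNPA1 and HNRNPA3 are the closest relatives of HNRNPA2B1 in the family. Of 20 m6A genes, the demethylase FTO (0.32) and the reader IGF2BP3 (0.25) rose and the nuclear reader YTHDC1 (-0.26) fell, also adjusted over the list alone (0.919; median -0.00, mean 0.01). Of 28 members of the insulin-like growth factor list, 4 rose, among them IGFBP3, IGFBP6 and IGF1R, and 4 fell (IGF2R, the adaptor GRB2, RPTOR and FOXO3), also adjusted over the list alone (0.780). IGFBP3, a secreted binding protein of the growth factor, went from 17.8 ± 0.746 to 45.2 ± 2.26 CPM (log2 fold change 1.31, SE 0.08, edgeR adjusted p = 1.1e-13), IGFBP6 by 0.32, IGF2R by -0.21 and GRB2 by -0.19. The SR splicing factors had 4 members up (SRSF5, SRSF11, SRSF6 and TRA2A) and 2 down (SRSF8 and TRA2B), also adjusted over the list alone (0.780; median -0.02, mean 0.03, test upward). SYNCRIP, RPTOR, FOXO3 and the SR genes were chosen after their values were seen.

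By camera, 8 of 29 lists passed after hnRNPA2B1 siRNA, 2 up and 6 down. With an estimated correlation 0 passed and 2 were below 0.05 unadjusted, and fry called 15. Fry does not set a list against the other genes, of which 30.4% were called here, so its count cannot be set beside that of camera. The ribosomal protein and oxidative phosphorylation lists, which passed camera, failed fry (fry adjusted p = 0.0996 each). In the G2/M list 17 of 35 members fell and 0 rose, also adjusted over the list alone, among them the mitotic kinase AURKB (-0.62), CDCA8 (-0.60), the survivin gene BIRC5 (-0.59) and the kinesin KIF2C (-0.46; camera adjusted p = 0.000112; adjusted p = 0.372 with an estimated correlation). NF-kB targets fell in 14 of 21 members, among them CSF2 (-1.46), TRAF1 (-0.88), the cytokine LIF (-0.52) and NFKB2 (-0.45), while VCAM1, CXCL8 and CXCL3 rose, also adjusted over the list alone (camera adjusted p = 0.00103; adjusted p = 0.44 with an estimated correlation). YAP/TEAD targets fell in 17 of 24 members, among them GADD45B (-0.73), NT5E (-0.60) and AMOTL2 (-0.48), while IGFBP3, AMOTL1 and F3 rose, also adjusted over the list alone (camera adjusted p = 0.000411; adjusted p = 0.372 with an estimated correlation). Immediate early genes fell in 8 of 22 members, among them FOSL1 (-0.59), KLF6 (-0.38) and the phosphatases DUSP1 (-0.34) and DUSP5 (-0.36), with 1 up and 8 down adjusted over the list alone (camera adjusted p = 0.0194; adjusted p = 0.682 with an estimated correlation). Nuclear-encoded oxidative phosphorylation genes fell in 10 of 34 members, among them CYC1 (-0.36), ATP5MC1 (-0.43) and COX5A (-0.34), while NDUFV2 (0.93), UQCRC2 and ATP5PB rose, also adjusted over the list alone (camera adjusted p = 0.0396; adjusted p = 0.697 with an estimated correlation). The immediate early list failed without sihnRNPA2B1-NC replicate 2 (adjusted p = 0.0692) or sihnRNPA2B1 replicate 2 (0.0679), and the oxidative phosphorylation list without sihnRNPA2B1-NC replicate 1 (0.0667), sihnRNPA2B1-NC replicate 2 (0.0741) or sihnRNPA2B1 replicate 1 (0.0871).

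The remaining 3 lists that passed bear on RNA composition. Mitochondrially encoded mRNAs rose in 11 of 13 members and fell in 0, also adjusted over the list alone, with MT-ND6 at 0.61, MT-ND5 at 0.55, MT-CO1 at 0.37 and MT-CO2 at 0.25 (camera adjusted p = 0.000156; adjusted p = 0.372 with an estimated correlation). Their share of counts was 6.36 ± 0.124% with the siRNA against 5.17 ± 0.0615% in the controls, higher in all 3 siRNA libraries than in any control. Cytosolic ribosomal protein genes fell in 24 of 46 members, among them RPS12 (-0.32), RPL10 (-0.30), RPL35 (-0.28) and RPS16 (-0.27), and rose in 2 (RPS3A and RPL22), with 4 up and 29 down adjusted over the list alone (camera adjusted p = 0.000744; adjusted p = 0.697 with an estimated correlation). Histone genes rose in 6 of 13 members, also adjusted over the list alone, with H2AC6 at 1.00, H4C8 at 0.97, H2BC5 at 0.96 and H1-2 at 0.53 (camera adjusted p = 0.00886; adjusted p = 0.372 with an estimated correlation). The other members named as rising against the direction of their list here and for the NF-kB, YAP/TEAD and oxidative phosphorylation lists were chosen after their values were seen.

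Called genes also lay in lists that did not pass after hnRNPA2B1 siRNA. Over all tested genes 30.4% were called, so a list with a share near that does not stand out by its count. In the hypoxia list 12 of 28 rose and 6 fell (camera adjusted p = 0.297), in the p53 list 3 of 26 rose (TP53INP1, FBXO22, ZMAT3) and 13 fell (0.0570), and in the G1/S list 1 of 32 rose (UNG) and 9 fell (0.0570). Of 23 cholesterol genes 1 rose (INSIG1) and 7 fell (0.0570), and of 16 heat shock genes 6 rose and 2 fell (HSF1, BAG3; 0.0570), 7 and 2 adjusted over the list alone. Glycolysis had 4 up and 6 down of 19 (0.619), fatty acid synthesis 2 up and 5 down of 23 (0.640), and autophagy 2 up and 9 down of 28 (0.173). The ATF4 list had 3 up and 7 down of 29 (0.364), 4 and 11 adjusted over the list alone, and the matrix list 7 up and 7 down of 25 (0.718), 8 and 7 adjusted over the list alone. Epithelial-mesenchymal genes had 5 up and 4 down of 24 (0.714), apoptosis genes 3 up and 8 down of 28 (0.261), kidney epithelial genes 6 up and 4 down of 18 (0.421) and receptor tyrosine kinases 3 up and 6 down of 18 (0.550; median -0.08, mean 0.00, test downward). In the interferon list 2 of 29 rose, among them IFIT5, and ISG15 and OAS3 fell (0.421), with 1 up and 2 down adjusted over the list alone. Among 5 small or nuclear non-coding RNAs MALAT1 (0.82) and NEAT1 rose and GAS5 and RN7SL1 fell (0.780), with 2 up and 3 down adjusted over the list alone. MAP2 rose among 6 neuronal markers (0.961; median -0.04, mean 0.11, test upward), LCP1 fell among 2 blood and immune markers, ROBO4 among 3 endothelial and SERPINA1 among 3 hepatocyte markers, and none of 3 fibroblast markers was called. The counts not given again were the same adjusted over the list alone, and the genes named in this paragraph were chosen after their values were seen. The p53 list passed without sihnRNPA2B1-NC replicate 2 (adjusted p = 0.0454) or sihnRNPA2B1 replicate 3 (0.0274), and the G1/S list without sihnRNPA2B1 replicate 1 (0.0440).

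**Figure D3:**
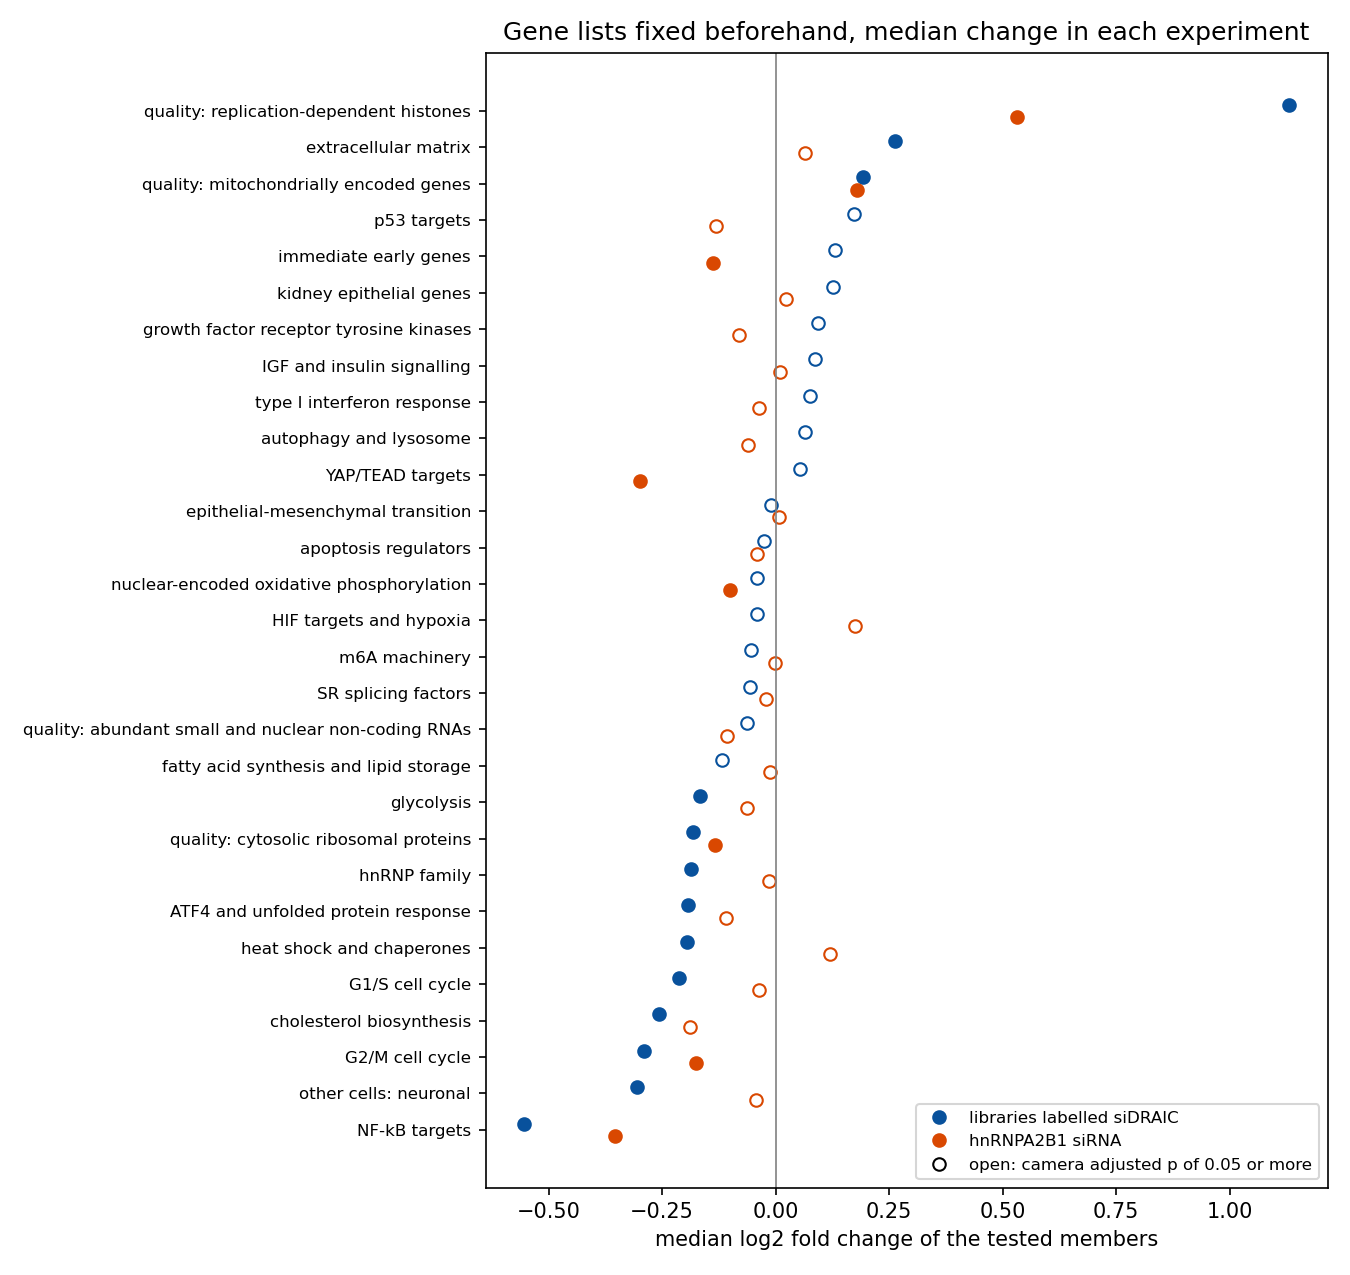
Median log2 fold change of the tested members of each gene list with at least 5 tested members (horizontal axis) in the libraries labelled siDRAIC (blue) and after hnRNPA2B1 siRNA (orange); filled points passed camera at an adjusted p below 0.05 and open points did not. The histone list lies at 1.13 and 0.53, and the NF-kB list at -0.55 and -0.35.

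Since the title links the 2 targets, the effects were compared gene by gene. They went in the same direction for most genes called in both experiments. Of 64 such genes, 59 moved the same way, such as CPA4, SLIT3, EDIL3, FBN1 and the endocytic receptor LRP1 (overlapping STAT6) upward and CD74, CTSS, UCA1, the complement protein C3 and the serine protease PRSS8 downward. The other 5 moved apart. PRSS23 (overlapping FZD4), the kinase SGK1 and TXNDC5 (overlapping BLOC1S5-TXNDC5) were higher in the libraries labelled siDRAIC and lower after hnRNPA2B1 siRNA, and CA12 and AKR1B10 the reverse.

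CD74 was at 0.421 ± 0.161 CPM against 1.89 ± 0.847 after hnRNPA2B1 siRNA (log2 fold change -2.17, edgeR adjusted p = 2.7e-05), and CTSS at 0.641 ± 0.309 against 3.29 ± 0.149 (-2.41, edgeR adjusted p = 5.9e-08). LRP1 rose by 1.59 in the libraries labelled siDRAIC and by 0.57 after hnRNPA2B1 siRNA, C3 changed by -1.12 and -0.57 and PRSS8 by -1.85 and -1.58. Called in both, 46 genes rose where independent lists would share 12.4, 13 fell where they would share 3.19, 3 were up and down where they would share 12.7 and 2 down and up where they would share 3.10. With the block in the DRAIC experiment, 758 of 1324 called genes were also called after hnRNPA2B1 siRNA, 677 in the same direction. This overlap has to be set against the 30.4% of all tested genes that were called after hnRNPA2B1 siRNA. Across the 14962 genes tested in both, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.378 and a Spearman correlation of 0.349, and 63.2% had the same sign. The experiments share no control library. The Pearson correlation was 0.0892 with DESeq2 and 0.0755 without the low-count filter, where genes near 0 counts enter; over the genes of the default filter those fits gave 0.378 and 0.379, a restriction chosen after seeing the data.

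**Figure D4:**
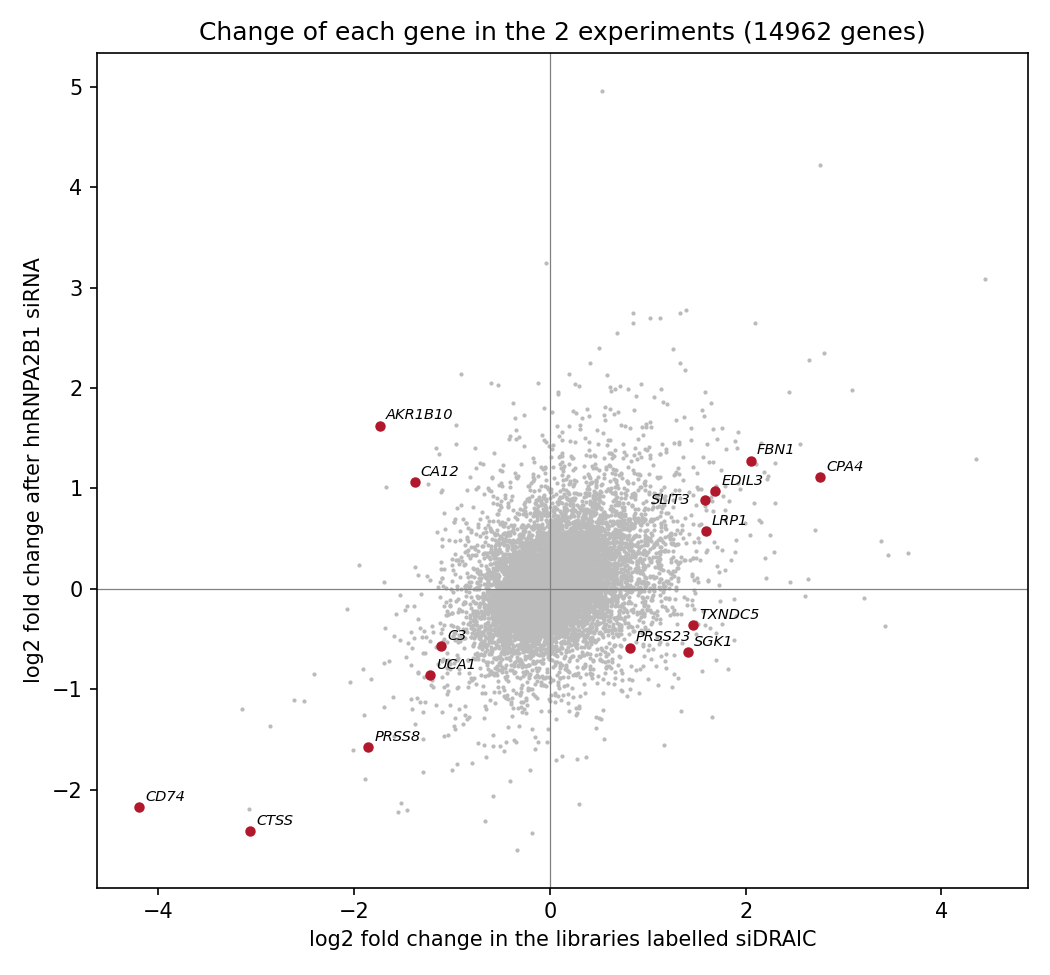
Log2 fold change of each of the 14962 genes tested in both experiments (points), in the libraries labelled siDRAIC on the horizontal and after hnRNPA2B1 siRNA on the vertical axis, with the named genes called in both in red. CD74 lies at -4.19 and -2.17, CPA4 at 2.76 and 1.11 and CA12 at -1.38 and 1.07.

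A test of the difference between the 2 changes asked which genes responded unequally. MMP2 rose in the libraries labelled siDRAIC and measured 4.60 ± 0.995 against 4.78 ± 0.703 CPM after hnRNPA2B1 siRNA, a difference of 3.27. CA12 fell in the former and rose from 33.2 ± 2.66 to 71.0 ± 5.89 CPM in the latter, a difference of -2.49. The siDRAIC and sihnRNPA2B1 libraries ended close for CA12, at 64.2 and 71.0 CPM, while their controls lay apart, at 165 and 33.2 CPM. AKR1B10 likewise lay at 3.10 and 3.47 CPM with the siRNAs and at 10.4 and 1.10 CPM in the controls. For MMP2 the controls lay closer, at 7.41 and 4.78 CPM. The test cannot tell an unequal response from an unequal start of the controls. The hypoxia-inducible factor EPAS1 rose from 31.6 ± 0.240 to 73.7 ± 4.76 CPM after hnRNPA2B1 siRNA (log2 fold change 1.19) and measured 13.9 ± 2.93 against 19.4 ± 3.70 in the libraries labelled siDRAIC. A total of 36 of 17091 genes differed, 18 in each direction.

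The smallest p belonged to PRSS23 (difference 1.37), CA12 and AKR1B10 (-3.39), each at an edgeR adjusted p of 0.000602. Next on the upper side came MMP2 (edgeR adjusted p = 0.00269), MN1 (difference 1.95), the secreted ligand WNT9A (1.44) and ARHGEF37 (1.56, edgeR adjusted p = 0.0086). On the lower side came NDRG1, a gene induced by hypoxia (-1.34), EPAS1 (-1.73, edgeR adjusted p = 0.0086) and GUCY1B1, a subunit of soluble guanylate cyclase (-1.21, edgeR adjusted p = 0.0258). The block gave 258 genes, DESeq2 188 and the unfiltered fit 263. Leaving out siDRAIC-NC replicate 1 gave 349 and siDRAIC-NC replicate 3 gave 14, and without sihnRNPA2B1-NC replicates 1, 2 and 3 there were 9, 9 and 10 genes, without sihnRNPA2B1 replicates 1, 2 and 3 there were 11, 9 and 10. All named genes but GUCY1B1 kept the call in each of these 12 fits. GUCY1B1 lost it without siDRAIC-NC replicate 3 (edgeR adjusted p = 0.0576), siDRAIC replicate 1 (0.0658), sihnRNPA2B1-NC replicates 1, 2 and 3 (0.104, 0.121 and 0.0579) and sihnRNPA2B1 replicates 1, 2 and 3 (0.117, 0.0675 and 0.0707).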

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

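The tests in this part were planned, except the tally of which drawn splits held a real split and the test on splits that part all numbered pairs, which were chosen only after the result was seen. The formal test for an outlying library needs 4 in a group and was not run on these groups of 3. The 10 genes here drew attention because their changes in the 2 experiments differed in a test of the difference itself. The change in the libraries labelled siDRAIC lay above that after hnRNPA2B1 siRNA by 1.37 for PRSS23, 3.27 for MMP2, 1.95 for MN1, 1.44 for WNT9A and 1.56 for ARHGEF37 on the log2 scale. It lay on the other side for CA12 (-2.49), AKR1B10 (-3.39), NDRG1 (-1.34), EPAS1 (-1.73) and GUCY1B1 (-1.21).

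Chance was not excluded for the number of genes with unequal change: of 100 drawn splits of the libraries within the 2 experiments, 10, the real one included, gave at least the real 36 genes, and the highest other gave 3463, which points to a structure of the samples. Of the 9 others, 5 kept the real hnRNPA2B1 split, 1 of them with the real DRAIC split reversed. Keeping the real hnRNPA2B1 split did not alone give as many, since 12 drawn splits, the real one included, kept it. The other 4 were among 77 with neither real split, the highest at 450. All of the 9 but the reversed one used DRAIC splits that mix the numbered pairs. Of the 80 splits that part all 3 DRAIC pairs, 2 reached 36, the real one and the reversed one (1483), and the highest of the rest gave 15; with the block the real split gave 258, the reversed one 2908 and the highest of 30 others 5. With the real hnRNPA2B1 split held, 8 such splits remain, too few for a share under 0.05.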

How the results depend on the processing

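The values of the correlation over default-filter genes were chosen only after the result was seen; all else here was planned. In the libraries labelled siDRAIC the 114 called genes became 381 with DESeq2, 45 with limma-voom, 520 without the filter, 61 with the strict filter, 1404 with the replicate block, 665 with all 12 libraries in 1 fit and 9 to 1035 without 1 library. After hnRNPA2B1 siRNA the 4781 became 283 with all 12 libraries and 449 with the 2-fold threshold, and 3318 to 5500 without 1 library. Genes with unequal change (36) became 188 with DESeq2, 263 without the filter, 258 with the block and 9 to 349 without 1 library. The correlation (0.378) was 0.0892 with DESeq2 and 0.0755 without the filter, both from genes near 0 counts (0.378 and 0.379 over the default genes), 0.447 with the strict filter, 0.460 at 5 CPM or more and 0.273 to 0.436 without 1 library. Lists past camera in the libraries labelled siDRAIC (13) became 0 with an estimated correlation, 0 with fry and 7 to 12 without 1 library, and those after hnRNPA2B1 siRNA (8) became 0 and 15. IGF1R in the libraries labelled siDRAIC was 0.87 with DESeq2, 0.87 without the filter, 0.91 with the block and 0.74 to 1.02 without 1 library; after hnRNPA2B1 siRNA it was 0.21 to 0.33. Except for fewer or other genes or libraries entering a fit, the cause was not tested.

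In the DRAIC experiment the block changed no call of the 29 genes named for it. Of 59 genes named anywhere and not called there, it called 19 (8 up, 11 down), each in its unblocked direction, among them IGF1R, IGFBP3 (edgeR adjusted p = 0.0638 without and 1.1e-12 with the block), CLDN2 (0.105 and 1e-05), EPHA7 (0.105 and 6.6e-17) and NDRG1 (0.176 and 0.000513). It changed no other call or count beyond those given with the results. In the hnRNPA2B1 experiment the same-numbered pairs correlated at -0.0117, -0.0242 and -0.0456 and the others at -0.00462 to 0.0291, so no sample correlated best with its own number, and the block gave 4414 calls. No called named gene changed direction under any alternative. DRAIC, not called, did: its log2 ratio of 0.82 in the libraries labelled siDRAIC was -0.10 to 1.38 without 1 library, below 0 without siDRAIC replicate 2, and that of -0.16 after hnRNPA2B1 siRNA was -0.64 to 0.25, above 0 without sihnRNPA2B1-NC replicate 1 (0.11) or 3 (0.00) or sihnRNPA2B1 replicate 3. DESeq2, no filter and the block kept all 29, 73 and 10 calls named for the DRAIC experiment, hnRNPA2B1 siRNA and the difference; of the 29, RLE factors lost 5, limma-voom 10 and the strict filter 6, and of the others none was lost. For DRAIC itself RLE, limma-voom, the strict filter and the block gave no value, since it fell below the filter, and at 0 to 8 counts its depth decides that no change was detectable.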

Other observations

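Tests chosen only after their results were seen were those of a batch shared by same-numbered libraries, of a swap, of a wrong label and of immune cells, the correlation with trends or list members removed, the tally of DRAIC splits against the real hnRNPA2B1 split, the comparison of the controls of the 2 experiments and the reading of MALAT1. The control groups of the 2 experiments differed from each other widely, although the labels give both as the same cell line. Between siDRAIC-NC and sihnRNPA2B1-NC, 8827 of 17091 genes (51.6%) differed in edgeR, 4550 higher and 4277 lower in siDRAIC-NC. TXNIP, which binds thioredoxin and responds to glucose, was lower in siDRAIC-NC by -4.15 on the log2 scale (edgeR adjusted p = 8.1e-10), and the PCNA-associated factor PCLAF higher by 4.20 (edgeR adjusted p = 5.1e-09). CD74 (3.02, edgeR adjusted p = 1e-05), named for the DRAIC experiment, also started higher there, as did HNRNPA2B1 (0.90, edgeR adjusted p = 1.9e-05). CXCL12 had 51, 29 and 18 counts in siDRAIC-NC and 4, 0 and 0 in sihnRNPA2B1-NC, and IGF1R differed by 0.20 (edgeR adjusted p = 0.226). Experiment and batch cannot be told apart in this comparison, and it enters no result within the 2 experiments. The test of the difference between the 2 changes does rest on both control groups.

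In the DRAIC experiment MALAT1, an abundant nuclear non-coding RNA, followed the replicate number more than the group. It measured 332, 140.3 and 111 CPM in siDRAIC-NC replicates 1, 2 and 3 and 335, 142.5 and 109.6 CPM in siDRAIC replicates 1, 2 and 3.

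The splits of 6 libraries into 3 and 3 are too few to give a share under 0.05. The real split, 1 of 10, had 114 genes in the libraries labelled siDRAIC and 4781 after hnRNPA2B1 siRNA, and the highest other split had 0 in edgeR in each, with up to 3678 and 814 genes below an unadjusted p of 0.05. The real splits had 1713 and 6297 such genes, so by this unadjusted count the real DRAIC split was not the highest. The 3678 came from siDRAIC-NC replicate 1 grouped with siDRAIC replicates 1 and 3. For the gene lists, likewise 1 of 10, the real splits had 13 and 8 lists and the highest others 7 and 3. Among splits that part all numbered pairs, with the block, the real DRAIC split called 1404 genes and each of the 3 others, which exchange the groups within 1 pair, 0 (432 at most unadjusted).

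In the DRAIC experiment siDRAIC-NC replicate 1 stood apart from the other controls, at -18.8 on the first principal component (37.4% of variance) against 35.7 and 49.9, and leaving it out raised the calls to 1035. The siDRAIC libraries lay at -40.1, -23.7 and -3.03, so siDRAIC-NC replicate 1 fell within their range there. On the second component (26.6%) it lay apart from all other libraries, at -46.7 against -9.68 to 35.5. A swap with a siDRAIC library is argued against. On a scale from controls (0) to siDRAIC (1), siDRAIC-NC replicate 1 lay at a median of 0.804 over 1022 genes. No siDRAIC library lay near the controls, the lowest at 0.769. The siDRAIC positions rest on only 23 to 93 genes, called with siDRAIC-NC replicate 1 among the controls. An unmixed siDRAIC library under a wrong label is argued against too, since over 273 genes called between replicates 2 and 3 alone siDRAIC-NC replicate 1 had a median position of 0.458 (quartiles 0.174 to 0.813) against 0.975 (0.823 to 1.18) for siDRAIC replicate 1, and lay nearer the controls than it in 265. A batch shared by same-numbered libraries remains a candidate explanation, since the lowest same-number correlation was 0.227 and the highest other 0.103, and a mixed library was not tested. The design gives no biological explanation for this pattern, and none was tested.

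The correlation of the 2 effects (0.378) was reached in absolute size by 2 of 100 pairs of splits, the real one included, a share under 0.05, but most of these pairs exchange hnRNPA2B1 libraries as well and do not test the DRAIC grouping alone, so chance is not taken as excluded. With the real hnRNPA2B1 split held, 2 of 10 DRAIC splits reached it, too few for a share under 0.05: the real one and, at 0.407, one that exchanges siDRAIC-NC replicate 1 and siDRAIC replicate 3, while the highest of the 3 others that part all numbered pairs was 0.347. Trends with transcript length and GC content are argued against as the cause, since the correlation was 0.387 with both removed. A joint shift of the cell cycle and RNA quality lists stays open, since their 142 members, 0.949% of the genes, are too few for leaving them out (0.376) to decide it. A response to any siRNA and a pathway that DRAIC and hnRNPA2B1 share may each stand behind it and were not tested.

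The fall of CD74, CTSS and LAPTM5 in the libraries labelled siDRAIC could come from immune cells in their controls. That is argued against by most markers, since the median of the 20 blood and immune markers there was 0 CPM, with ITGAM at 3.57, LCP1 at 1.42, CSF1R at 0.889, PTPRC at 0.0568 and LYZ and CD52 at 0, against 15.1 for CD74, 12.3 for CTSS and 4.19 for LAPTM5. Not all values go against it, since ITGAM was near LAPTM5. The 3 markers of that list above the filter all had estimates below 0 in the libraries labelled siDRAIC (median log2 fold change -1.22), with none called over all genes. The unequal start of CD74 in the 2 control groups stays unexplained.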
